A study of Mus musculus with 12 samples.

How the data were processed

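Total RNA of mouse embryonic fibroblasts was measured on 12 Illumina bead arrays, 2 arrays in each of 6 groups. Per the labels' protocols, 100 ng of RNA was amplified and labelled with biotin for each array. The deposited table of non-normalized values gives, per the file headers, a mean bead signal intensity and a detection p-value for each of 25697 probes on each array. The deposited detection p-values rise in steps of 1 in 798, as ranks among 798 negative controls would. The lowest signals, 34.1 to 40.8, lie above 0 and the array medians differ, from 66.6 to 87.0, so these intensities, as deposited by the authors, show neither background subtraction nor normalization between arrays. The authors' processed table also holds intensities on a linear scale. In it, 11 of 12 columns share the same sorted distribution (largest log2 difference under 0.001), with a median of 80.2, as quantile normalization gives. The column of WT L0 replicate 2 equals its non-normalized signal for 100% of probes, with a median of 87.0. The submitters' processing notes name limma without a version or a role, and the software that made the non-normalized table is not given in the sources used here.

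Groups were taken from the titles of the samples: a WT and a YYFF clone, each before laminin (L0) and after 4 (L4) or 8 (L8) passages on it. The titles and the descriptions both number the replicates, and these numbers match in 3 of 6 groups; the titles' numbers are used here. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Each genotype is represented by a single clone, so genotype and clone are the same contrast, and cells with more laminin passages were also longer in culture.

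The non-normalized intensities were background-corrected by normexp with negative control parameters inferred from the detection p-values (offset 16), quantile-normalized and log2-transformed, with limma 3.58.1 in R 4.3.3. Probes were kept if their detection p was under 0.05 on at least 2 of 12 arrays, which left 12974. The platform annotation gave 1 gene symbol for 23978 probes, several for 0 and none for 1719. Symbols were updated through the RefSeq gene table of assembly GRCm38.p6, to which 23962 of the named probes matched by Entrez ID and 9 by accession; 7 kept the name of the platform annotation. That table served only for names, chromosomes and the order of neighbouring genes. Of the detected probes of each gene, the probe with the highest mean over the 12 arrays was tested, giving 8891 genes, of which 2343 had more than 1 detected probe.

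A limma model with 1 coefficient per group (12 arrays, 6 residual degrees of freedom, 2.91 prior degrees of freedom, median residual SD 0.161 on the log2 scale) gave every contrast, with eBayes and Benjamini-Hochberg adjustment over the 8891 genes and a threshold of 0.05. The contrasts were L4 vs L0, L8 vs L0 and L8 vs L4 within each genotype, YYFF vs WT at each passage number, and the difference between the genotypes in the L4 and L8 changes (interaction). Values after ± are SEs of a log2 change from this model unless called SD, and n is 2 arrays per group throughout. The number of arrays limits the precision. Gene lists (34, of which 30 had at least 5 tested genes) and the 20 chromosomes with at least 20 tested genes were tested with limma's camera with a preset correlation between genes of 0.01, and again with the correlation estimated from the data. Counts for a list are given over all genes tested and, where they differ, adjusted over the list alone. A gene not above background on either array of a group has only a bound there. For such genes the mean of the brighter group is set against the mean, over the arrays of the dimmer group, of the higher of the gene's own value and the lowest normalized value of any probe above background on that array, and the result is written as "at least N-fold".

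Lists, the test of each comparison, the alternatives below except those named as added, and the rule for naming genes were fixed before the data were examined. The rule named Itgb1 first; then, per comparison, the largest changes in each direction among genes above background on every array compared and past the threshold with any 1 of those arrays left out; then up to 3 genes per direction detected in only 1 of the groups compared; then up to 4 members per list past the threshold; and genes of X inactivation and the Y chromosome as a check of the label female. Unnamed predicted genes were passed over. The text gives a part of the genes so named.

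The model was tested on simulated data built on YYFF L8 vs L0 (8891 genes, 200 changed, 2 arrays per group). It found 19.4% of genes changed by 0.5 on the log2 scale, 76.1% of those changed by 1 and 100% of those changed by 2, with 0 in the wrong direction and 4 unchanged genes called. A simulated shift of 0.2 over the 381 genes of chromosome 15 was found in the same comparison, with 0 other chromosomes called. The noise of these simulated genes was independent, and besides that shift only 200 genes changed, against 3234 called in the real comparison. These simulations therefore cannot tell how often genes or chromosomes are missed or falsely called in the real data. Alternatives were no background correction, median scaling, no filter, a stricter filter, the authors' processed values, every detected probe, the replicate number as a block, the compared arrays alone, array weights, and each array left out in turn. Added after seeing the data were the tests of explanations in the closing section, list medians with genes set at their bound, the authors' values with all columns quantile-normalized, a mean-variance trend with a robust prior, and a search for stretches of neighbouring genes that shift together. That search split the gene order of each chromosome wherever a stretch of at least 20 genes differed from the rest by more than in any of 20 permutations of the gene order, with single genes limited to a log2 change of 1. In simulated data for YYFF L4 vs L0 (8887 genes) it recovered a shift of 0.5 over 81 genes to the exact gene, with 0 false breaks on other chromosomes. The shift was placed on chromosome 19, near the stretch reported below. The simulated genes had independent residual noise only, without the real spread of changes or the correlation of neighbouring genes. The simulation therefore cannot tell how often the search makes false breaks in the real data. Figures were drawn with matplotlib 3.10.9.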

Results

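Gene expression was measured in fibroblasts from female C57BL/6 mouse embryos, immortalized with the large T antigen of SV40. The integrin β1 subunit is part of receptors through which cells bind laminin. The YYFF clone carries a mutated β1 integrin with which, per the labels' protocols, cells fail to divide the cytoplasm on a matrix bound by β1 integrins alone, and the WT clone carries the normal subunit. Cells were plated on laminin 0, 4 or 8 times and then grown on plastic, with 2 arrays in each of the 6 groups. The total signal per array was 13197182 to 17683779, and 10392 to 11766 probes (40.4% to 45.8%) were above background. Over the 8891 genes tested, replicates correlated across genes with r of 0.987 (YYFF L8) to 0.994 (YYFF L0). The title of the series names the effect of aneuploidy on gene expression as its subject.

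Itgb1, which encodes the β1 subunit, was above background on all 12 arrays. Its normalized log2 signal (mean ± SD) was 9.07 ± 0.05 in WT L0, 8.55 ± 0.25 in WT L4, 8.31 ± 0.13 in WT L8, 9.05 ± 0.21 in YYFF L0, 9.11 ± 0.08 in YYFF L4 and 8.83 ± 0.04 in YYFF L8. Itgb1 fell by 0.77 ± 0.15 on the log2 scale in WT L8 vs L0 (adjusted p = 0.0036). Its change in WT L4 vs L0 was -0.53 ± 0.15 (adjusted p = 0.043), and it missed the threshold without WT L4 replicate 1 (adjusted p = 0.204), WT L0 replicate 2 (0.161) or WT L0 replicate 1 (0.124). At L0 the clones differed by -0.02 ± 0.15 (adjusted p = 0.945). A dimmer Itgb1 probe, also above background on all 12 arrays, differed from this one. In a limma fit of every detected probe it gave -1.42 ± 0.38 in YYFF L8 vs L0 (adjusted p = 0.0184; 6.75 and 8.16 on the L8 arrays, 8.83 and 8.93 on the L0 arrays), against -0.23 ± 0.15 (adjusted p = 0.293) for the brighter probe. In WT L8 vs L0 the dimmer probe gave -0.62 ± 0.38 (adjusted p = 0.247), the same direction with a larger error, so the call in WT rests on the brighter probe. In that fit YYFF vs WT gave 0.56 ± 0.15 at L4 (adjusted p = 0.019) and 0.52 ± 0.15 at L8 (adjusted p = 0.026) for the brighter probe. The dimmer probe gave 0.52 ± 0.38 (adjusted p = 0.336) and -0.69 ± 0.38 (adjusted p = 0.197). The interaction passed for neither probe (brighter probe: adjusted p = 0.093 at L4 and 0.092 at L8). The fall in WT was thus not shown to differ from YYFF. The probes measure the amount of transcript and cannot show the YYFF change itself. Xist, the RNA that coats the inactive X chromosome, was above background on 6 of 6 WT arrays and on 0 of 6 YYFF arrays. Xist was at least 9.25-fold lower in YYFF than in WT at L0 (adjusted p = 7.96e-08), and within WT it fell by 1.13 ± 0.11 in L8 vs L0 (adjusted p = 0.000102). Of Y-linked genes, Eif2s3y, Kdm5d, Zfy1 and Sry were above background on 0 of 12 arrays, while the Uty probe gave a dim signal of 5.80 to 6.59 on all 12 arrays of both genotypes.

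**Figure D1:**
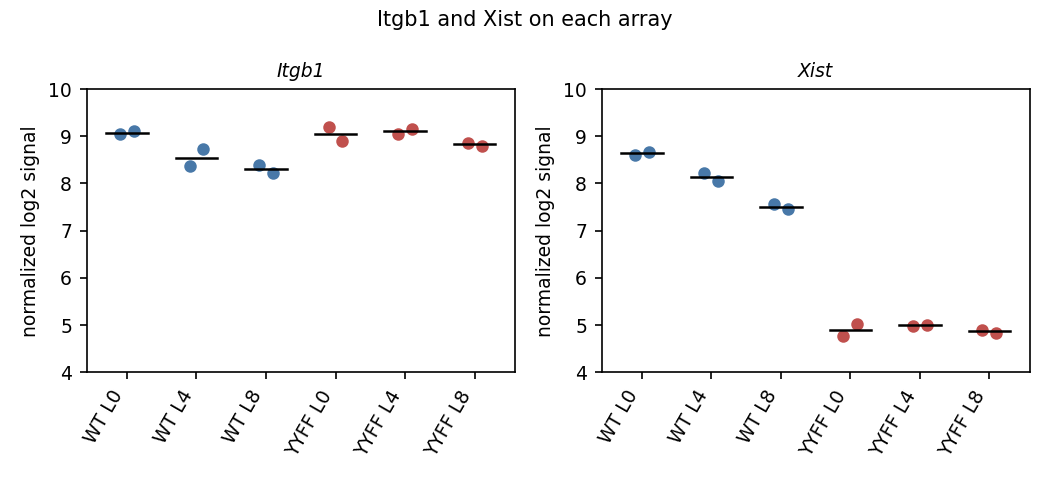
Normalized log2 signal of Itgb1 (left) and Xist (right) on each array (points) with the group mean (line), WT in blue and YYFF in red. Xist lies between 7.46 and 8.67 on the WT arrays and between 4.76 and 5.03 on the YYFF arrays, where it is not above background.

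The comparison of YYFF cells after 8 laminin passages with the same clone before them spans laminin passage and longer culture together. It cannot single out what failure of division on laminin leaves behind. Interferon response genes, the antiviral program, fell as a group: 29 of 31 tested fell and 1 rose, with a median log2 change of -2.36 (-2.05 with 8 genes set at their bound). Examples are Igtp (-4.41 ± 0.15), Usp18 (-4.33 ± 0.11), Oasl2 (-4.10 ± 0.13) and Isg15 (-3.34 ± 0.14). Genes of cholesterol synthesis rose in 16 of 17 cases (17 of 17 adjusted over the list alone), with a median of 1.57, among them Mvd (2.22 ± 0.17), Insig1 (2.13 ± 0.17), Nsdhl (2.07 ± 0.18) and Lss (2.06 ± 0.18). Of 22 serum response and contractile genes, 17 fell (18 adjusted over the list alone) and 1 rose, with Tagln (-3.89 ± 0.13), Lmod1 (-3.53 ± 0.13), the smooth muscle actin Acta2 (-3.08 ± 0.11) and Actg2 (-2.80 ± 0.20) leading. Of 24 targets of p53, 17 fell and 0 rose (median -1.06, and -0.96 with 1 gene at its bound), including the cell cycle inhibitor Cdkn1a (-2.40 ± 0.15), Trp53inp1 (-3.68 ± 0.10) and the death receptor Fas (-3.64 ± 0.13). The adjusted p of camera for these 4 lists was 8.74e-16, 1.76e-10, 2.5e-08 and 1.62e-07, and 0.00725, 0.00725, 0.00928 and 0.0192 with an estimated correlation.

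In YYFF L8 vs L0 Ly6c1, a surface protein anchored by lipid, rose by 4.90 ± 0.12, and the glutathione transferase Gsta1 by 4.67 ± 0.30. AA467197 (4.66 ± 0.62), the semaphorin receptor Plxna2 (3.80 ± 0.18), the proteoglycan decorin, Dcn (3.43 ± 0.10), integrin β7, Itgb7 (3.32 ± 0.22), and Nnmt (3.15 ± 0.38) also rose. Matrix Gla protein, Mgp (-5.58 ± 0.16), the gap junction gene Gjb2 (-5.18 ± 0.10), the chemokine Cxcl12 (-5.08 ± 0.14), Ifi27l2a (-4.52 ± 0.29), Rcan2 (-4.50 ± 0.13), the receptor ligand Gas6 (-4.43 ± 0.13) and osteoglycin, Ogn (-4.19 ± 0.10), fell. Gna14 (at least 18.9-fold), Gsta2 (at least 17.1-fold) and the hyaluronan synthase Has1 (at least 16.0-fold) were above background on both L8 arrays and neither L0 array. Apod (at least 37.9-fold), the netrin receptor Unc5c (at least 27.5-fold) and the Wnt agonist Rspo3 (at least 26.3-fold) showed the opposite.

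Smaller shifts in YYFF L8 vs L0 passed the camera test and were lost with an estimated correlation. Of 12 imprinted genes, 7 fell (8 adjusted over the list alone) and 1 rose (median -0.71, and -0.57 with 5 genes at their bound; adjusted p = 0.0623 with an estimated correlation), with Dlk1 (-4.89 ± 0.09), Igf2 (-4.67 ± 0.12) and Mest (-3.47 ± 0.25) lower and Dcn higher. Glycolysis and hypoxia genes rose in 10 of 23 cases (11 adjusted over the list alone; median 0.38, adjusted p = 0.072 with an estimated correlation), among them Ndrg1 (1.73 ± 0.11). Proteasome genes rose in 8 of 28 cases (6 adjusted over the list alone; median 0.23, adjusted p = 0.0819 with an estimated correlation). TGF-β and BMP pathway genes fell in 15 of 25 cases (median -0.48, and -0.37 with 3 genes at their bound; adjusted p = 0.113 with an estimated correlation), including Fst (-3.19 ± 0.18) and Grem1 (-2.20 ± 0.17). NRF2 and antioxidant genes rose in 9 of 24 cases (11 adjusted over the list alone; median 0.42, adjusted p = 0.153 with an estimated correlation), while Hmox1, which breaks down heme, fell by 2.74 ± 0.13. Basement membrane genes fell in 7 of 13 cases (8 adjusted over the list alone; median -0.41, adjusted p = 0.234 with an estimated correlation), led by Col18a1 (-4.66 ± 0.16) and Nid2 (-3.84 ± 0.13). This list missed the threshold without YYFF L8 replicate 2 (adjusted p = 0.0577). Lists of interstitial matrix and of heat shock genes passed with adjusted p of 0.0382 and 0.0496 (adjusted p = 0.305 and 0.234 with an estimated correlation), and missed the threshold without YYFF L0 replicate 2 or YYFF L8 replicate 2 (at most 0.0555 and 0.0903), the heat shock list also without YYFF L8 replicate 1. In all, 3234 of 8891 genes changed, 1520 higher and 1714 lower, 1070 of them at least 2-fold. With median scaling the split was 795 higher and 1386 lower, and with the stricter filter 1344 higher and 1200 lower.

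After 4 laminin passages the YYFF cells already showed these shifts. Interferon response genes fell in 28 of 31 cases with a median of -2.54, or -2.13 with 9 genes at their bound (Oasl2 -4.86 ± 0.13, Usp18 -4.66 ± 0.11), and cholesterol synthesis genes rose in 17 of 17 cases with a median of 1.49 (Insig1 2.83 ± 0.17, Nsdhl 2.53 ± 0.18). Targets of p53 fell in 15 of 24 cases (16 adjusted over the list alone; Fas -3.44 ± 0.13, Mdm2 -1.75 ± 0.12) and serum response and contractile genes in 16 of 22 cases (17 adjusted over the list alone; Lmod1 -3.41 ± 0.13, the early response gene Egr1 -2.62 ± 0.12). All 4 lists held with an estimated correlation (adjusted p = 0.0045, 0.0045, 0.0174 and 0.0131). Lost with an estimated correlation were imprinted genes (8 of 12 fell and 2 rose, median -0.54, and -0.50 with 5 genes at their bound; adjusted p = 0.0971 with an estimated correlation), TGF-β and BMP pathway genes (median -0.30), NRF2 genes (0.40), glycolysis and hypoxia genes (0.39) and proteasome genes (0.16), the last 4 with adjusted p = 0.163, 0.151, 0.139 and 0.135 with an estimated correlation. Without YYFF L4 replicate 2 these 4 missed the threshold (adjusted p of 0.0535, 0.0535, 0.0535 and 0.0647), and proteasome genes also did without YYFF L0 replicate 2 (0.0504). Has1 (at least 19.1-fold) and the phosphatase gene Dusp4 (at least 15.4-fold) rose from background, Apod (at least 40.0-fold) and Gas6 (at least 31.2-fold) fell to it, and the growth factor gene Ptn fell by 4.81 ± 0.22. In YYFF L4 vs L0, 2803 genes changed, 1278 higher and 1525 lower, 906 of them at least 2-fold. With median scaling the count was 1789, and with the stricter filter the split turned to 1129 higher and 1098 lower.

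Between 4 and 8 passages the YYFF cells changed little. Gsta2 (2.15 ± 0.12), Elmod1 (1.47 ± 0.19), Smoc1 (1.44 ± 0.17) and Pip5k1b (1.39 ± 0.11) rose, and Cxcl12 (-1.93 ± 0.14), the cytokine signalling inhibitor Cish (-1.84 ± 0.13) and the chemokine Ppbp (-1.74 ± 0.12) fell. In YYFF L8 vs L4, 128 genes changed, 36 higher and 92 lower, against 1449 at an unadjusted p under 0.05. The count was 35 without YYFF L4 replicate 1, 45 without YYFF L4 replicate 2 and 213 without YYFF L8 replicate 2, 69 with median scaling and 201 with the stricter filter. With the 4 compared arrays alone limma called 0 genes, against 1082 at an unadjusted p under 0.05.

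**Figure D2:**
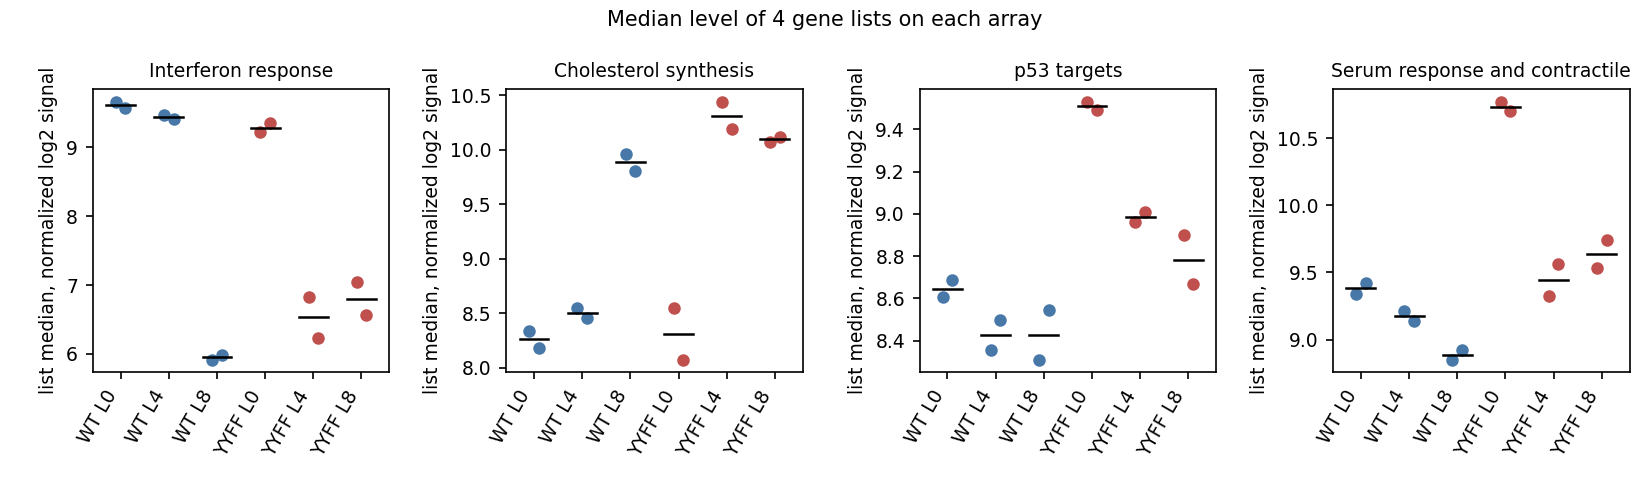
Median normalized log2 signal over the tested genes of 4 lists on each array (points) with the group mean (line), WT in blue and YYFF in red. The interferon list lies between 9.22 and 9.66 in WT L0, WT L4 and YYFF L0 and between 5.92 and 7.04 in the other groups, and the cholesterol list is between 8.08 and 8.55 in the former and between 9.80 and 10.4 in the latter.

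In the WT clone, the comparison with L0 shows what the same handling does to cells with normal β1 integrin. After 8 passages interferon response genes fell in 25 of 31 cases with a median of -2.25 (-2.22 with 9 genes at their bound), led by Usp18 (-6.80 ± 0.11), Isg15 (-6.13 ± 0.14), Oasl2 (-6.02 ± 0.13) and Bst2 (-4.87 ± 0.33). Cholesterol synthesis genes rose in 16 of 17 cases (17 adjusted over the list alone) with a median of 1.60, led by Insig1 (2.59 ± 0.17), Mvd (2.55 ± 0.17) and Hmgcs1 (2.37 ± 0.14). Both held with an estimated correlation (adjusted p = 0.00541 for each). Of 22 serum response and contractile genes 12 fell, among them Ccn2 (-2.81 ± 0.09) and Myc (-2.24 ± 0.24), with an adjusted p = 0.0647 with an estimated correlation. Of 24 targets of p53 12 fell, among them Cdkn1a (-2.24 ± 0.15), and 2 rose (median -0.39, adjusted p = 0.176 with an estimated correlation). Basement membrane genes fell in 7 of 13 cases (9 adjusted over the list alone; median -0.36, adjusted p = 0.243 with an estimated correlation), with Agrn at -1.66 ± 0.11. NRF2 and antioxidant genes rose in 12 of 24 cases (14 adjusted over the list alone; median 0.44, adjusted p = 0.176 with an estimated correlation). Glycolysis and hypoxia genes rose in 11 of 23 cases (median 0.45, and 0.32 with 3 genes at their bound; adjusted p = 0.176 with an estimated correlation), and lysosome and autophagy genes in 11 of 31 (median 0.27, adjusted p = 0.149 with an estimated correlation). These 3 lists missed the threshold without WT L0 replicate 1 (adjusted p = 0.0718, 0.0913 and 0.0913), and glycolysis and hypoxia genes also without WT L8 replicate 2 (0.0918).

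Other genes that rose in WT L8 vs L0 were Pdlim4 (3.33 ± 0.18), Ly6c1 (3.32 ± 0.12), Aldh3b1 (3.26 ± 0.12), the glutathione transferase Gstm2 (3.21 ± 0.12) and Cbr2 (3.13 ± 0.21). The antiviral and interferon-induced genes Oas1g (-4.80 ± 0.11), Gbp3 (-4.78 ± 0.15) and Irgm2 (-4.08 ± 0.15), cyclin D2, Ccnd2 (-4.63 ± 0.25), and the chemokine Ccl5 (-4.37 ± 0.25) fell. The protease inhibitor Slpi rose from background at least 22.5-fold, and Fxyd6 fell to it at least 24.4-fold. In WT L8 vs L0, 3212 genes changed, 1640 higher and 1572 lower, 865 of them at least 2-fold. With median scaling the count was 2068, and with the authors' values the split turned to 1642 higher and 1696 lower.

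After 4 passages the WT clone had changed less. Dcn (3.56 ± 0.10), Ifi27l2a (3.17 ± 0.29), Olfml2b (3.14 ± 0.18), Rspo3 (3.09 ± 0.16) and the collagenase gene Mmp13 (2.98 ± 0.19) rose, and the deiodinase gene Dio3 (-3.20 ± 0.16), Scara3 (-2.80 ± 0.12), Rsad2 (-2.75 ± 0.13) and Fez1 (-2.71 ± 0.15) fell. Slpi (at least 23.6-fold) and Ppp1r1b (at least 18.1-fold) rose from background, while Ccnd2 (at least 25.6-fold), Fxyd6 (at least 22.8-fold) and the imprinted gene Ndn (at least 11.9-fold) fell to it. Interferon response genes fell in 17 of 31 cases (20 adjusted over the list alone; median -0.57) and targets of p53 in 10 of 24 (median -0.29), with adjusted p = 0.059 and adjusted p = 0.0928 with an estimated correlation. Serum response and contractile genes fell in 7 of 22 cases (10 adjusted over the list alone; median -0.20, adjusted p = 0.161 with an estimated correlation) and imprinted genes in 6 of 12 (median -0.39, adjusted p = 0.184 with an estimated correlation), the latter lost without WT L4 replicate 1 (adjusted p = 0.0639). In WT L4 vs L0, 1376 genes changed, 666 higher and 710 lower. The count was 683 with median scaling, 490 with the compared arrays alone, 740 without WT L0 replicate 1, 843 without WT L0 replicate 2 and 851 without WT L4 replicate 2. The split turned to 623 higher and 610 lower with the stricter filter, 485 and 443 without WT L4 replicate 1, and 429 and 422 without WT L4 replicate 2.

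From 4 to 8 passages the WT clone showed the interferon and cholesterol shifts: 24 of 31 interferon response genes fell (median -1.77, and -1.36 with 7 genes at their bound), and 16 of 17 cholesterol synthesis genes rose (median 1.55), each with adjusted p = 0.00234 with an estimated correlation. Usp18 (-5.96 ± 0.11), Isg15 (-5.29 ± 0.14), Mmp13 (-4.87 ± 0.19) and Gbp3 (-4.29 ± 0.15) fell, and Ly6c1 (2.83 ± 0.12), Gstm2 (2.65 ± 0.12), Hs3st3a1 (2.57 ± 0.12) and the iron exporter Slc40a1 (2.39 ± 0.13) rose. In WT L8 vs L4, 1745 genes changed, 957 higher and 788 lower. The count was 865 with median scaling, 890 with the compared arrays alone, 1132 without WT L4 replicate 2, 1023 without WT L8 replicate 1 and 887 without WT L8 replicate 2.

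The clones already differed before any passage on laminin. Targets of p53 were higher in YYFF L0 than in WT L0 for 17 of 24 genes and lower for 1 (median 0.84, adjusted p = 0.0428 with an estimated correlation), with Ephx1 (2.05 ± 0.09), Fas (2.05 ± 0.13), Gadd45a (1.84 ± 0.17) and Trp53inp1 (1.83 ± 0.10) leading. Serum response and contractile genes were higher in 10 of 22 cases (11 adjusted over the list alone; Actg2 5.13 ± 0.20, Lmod1 3.44 ± 0.13, adjusted p = 0.0741 with an estimated correlation). Basement membrane genes were higher in 10 of 13 cases (Col4a5 3.40 ± 0.18, Lamb3 1.64 ± 0.19, adjusted p = 0.161 with an estimated correlation). Interstitial matrix genes were higher in 12 of 21 cases (Ogn 3.68 ± 0.10, Col1a1 2.72 ± 0.15, adjusted p = 0.27 with an estimated correlation). Mitotic spindle and checkpoint genes were lower in 4 of 21 cases (median -0.27) and unfolded protein response genes higher in 5 of 22 (median 0.22), each with adjusted p = 0.161 with an estimated correlation. Without WT L0 replicate 1 both missed the threshold (adjusted p = 0.0639 and 0.0907), and the latter also did without WT L0 replicate 2 (0.0528), YYFF L0 replicate 1 (0.0664) or YYFF L0 replicate 2 (0.0671). Ifi27l2a (4.68 ± 0.29), Apod (4.61 ± 0.19) and the skeletal actin Acta1 (4.14 ± 0.16) were higher in YYFF, and the growth factor Artn (-4.74 ± 0.10), the stromelysin Mmp3 (-4.70 ± 0.16), podoplanin, Pdpn (-4.67 ± 0.15), and Igfbp4 (-4.23 ± 0.12) were lower. The complement inhibitor Cd59a (at least 52.3-fold higher), Gas6 (at least 32.8-fold higher) and Ednrb (at least 28.7-fold higher) were above background only on the YYFF arrays of this pair of groups. Tfap2a (at least 16.2-fold lower), the protease Ctsc (at least 16.0-fold lower) and Ndn (at least 13.5-fold lower) were above it only on the WT arrays. At L0, 2397 genes differed, 1311 higher and 1086 lower in YYFF. The count was 1418 with median scaling, 1554 without WT L0 replicate 1, 1505 without YYFF L0 replicate 1 and 1526 without YYFF L0 replicate 2. With the stricter filter the split turned to 965 higher and 985 lower.

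After 4 passages YYFF cells had lower interferon response genes than WT in 26 of 31 cases (median -1.41, and -1.10 with 5 genes at their bound) and higher cholesterol synthesis genes in 16 of 17 (17 adjusted over the list alone; median 2.04), both with adjusted p = 0.0107 with an estimated correlation. S100a7a (5.22 ± 0.15), the proteasome subunit gene Psmd8 (4.93 ± 0.30) and Tsc22d3 (4.37 ± 0.37) were higher in YYFF, and Pdpn (-5.75 ± 0.15), Mgp (-5.03 ± 0.16) and Cxcl12 (-4.98 ± 0.14) were lower. At L4, 3371 genes differed, 1618 higher and 1753 lower, and with median scaling the split turned to 1207 higher and 1064 lower. After 8 passages the small heat shock protein gene Hspb1 (5.44 ± 0.51), Psmd8 (4.73 ± 0.30), Ccnd2 (4.55 ± 0.25) and Ramp2 (4.23 ± 0.20) were higher in YYFF, and Cxcl12 (-6.72 ± 0.14), Pdpn (-6.30 ± 0.15), Mgp (-5.47 ± 0.16) and Igfbp4 (-4.99 ± 0.12) were lower. Of 23 DNA damage repair genes 12 were lower and 0 higher (1 higher adjusted over the list alone; median -0.44, adjusted p = 0.201 with an estimated correlation), among them Fanci (-1.15 ± 0.13) and Blm (-0.91 ± 0.10). Blm is also the last gene of a chromosome 7 stretch, given under other observations, whose 26 genes had a median of -0.81 here. Its difference cannot be told apart from the shift of that stretch. Heat shock and chaperone genes were higher in 11 of 26 cases (median 0.31, adjusted p = 0.381 with an estimated correlation), unfolded protein response genes in 10 of 22 (median 0.34, adjusted p = 0.201 with an estimated correlation) and interferon response genes in 11 of 31, with 3 lower (median 0.12, adjusted p = 0.381 with an estimated correlation). Without WT L8 replicate 1 all 4 lists missed the threshold (adjusted p = 0.0553 for repair, 0.0682 for heat shock, 0.0553 for unfolded protein response and 0.0682 for interferon response), and interferon response also did without YYFF L8 replicate 1 (0.0899). At L8, 3289 genes differed, 1525 higher and 1764 lower, and with median scaling 857 higher and 1398 lower.

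Of 30 lists tested per comparison, the number that passed with the preset correlation and the number that did so with an estimated correlation were 12 and 4 in YYFF L8 vs L0, 9 and 4 in YYFF L4 vs L0, and 8 and 2 in WT L8 vs L0. They were 10 and 2 in WT L8 vs L4, 6 and 0 in YYFF L8 vs L4, and 4 and 0 in WT L4 vs L0. Between the clones they were 6 and 1 at L0, 10 and 2 at L4 and 4 and 0 at L8. The list tests were not run with arrays left out for YYFF L8 vs L4, WT L8 vs L4 and YYFF vs WT at L4. With 1 array left out, the first number was 5 in YYFF L4 vs L0 without YYFF L4 replicate 2, 9 in WT L4 vs L0 without WT L0 replicate 2, 5 in WT L8 vs L0 without WT L0 replicate 1, and 0 between the clones at L8 without WT L8 replicate 1.

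The interaction asks whether the passage effect itself differed between the clones. From L0 to L4 interferon response genes fell more in YYFF than in WT (median difference -1.68, 21 of 31 genes lower and 2 higher; 23 lower adjusted over the list alone) and cholesterol synthesis genes rose more (median difference 1.60, 14 of 17 genes, 15 adjusted over the list alone), both with adjusted p = 0.0143 with an estimated correlation. From L0 to L8 neither list passed (median difference 0.19, adjusted p = 0.0992, and -0.30, adjusted p = 0.358). The p53 list did from L0 to L8, with 13 of 24 genes lower (median difference -0.71, adjusted p = 0.403 with an estimated correlation). The passage effect differed for 2109 genes at L4 and 2831 at L8. With median scaling these counts were 1295 and 1753, and the split at L8 was 607 higher and 1146 lower against 1276 and 1555.

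Across the 8891 genes, which are not independent replicates, the L8 vs L0 changes of YYFF and WT correlated with Pearson r of 0.22 and Spearman rho of 0.181 (simulated unchanged groups gave a mean r of 0.000289). Of the genes changed in both, 489 rose in both, 560 fell in both and 533 moved in opposite directions, where independent lists would give 280.4, 303 and 584.9. The L4 vs L0 changes of the clones correlated with r of 0.0786. Within YYFF the L4 and L8 changes correlated with r of 0.928 (simulated 0.499; covariance 0.563 against 0.0192), and 1012 genes rose and 1293 fell in both, with 3 opposite. Within WT the r was 0.687 (simulated 0.501; covariance 0.228 against 0.0193), and 523 genes rose and 533 fell in both, with 28 opposite. Independent lists would give 218.5, 294 and 507.1 genes within YYFF and 122.8, 125.5 and 248.7 within WT, and part of the excess of the counts over these may come from the shared L0 arrays. The covariance exceeded the simulated one, which holds that sharing, by 0.544 in YYFF and 0.208 in WT. These 4 are among 5 such relations computed.

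Genes were also grouped by chromosome, since gain or loss of a chromosome would move the median of its genes. In YYFF L4 vs L0 the genes of chromosome 15 (381 genes, median log2 change 0.23) and chromosome 19 (326 genes, 0.15) rose and those of chromosome 7 (679 genes, -0.16) and chromosome 14 (296 genes, -0.18) fell as groups. The camera adjusted p was 0.00219, 0.0162, 0.00219 and 0.0162, and 0.004, 0.00878, 0.011 and 0.0268 with an estimated correlation. In YYFF L8 vs L0 chromosomes 7 (-0.16) and 14 (-0.15) fell and chromosome 19 rose (0.20), with adjusted p = 0.0163, 0.0197 and 0.0129 with an estimated correlation. Chromosomes 15 (0.14), 16 (0.17) and 17 (-0.09) missed the threshold there with the preset correlation (adjusted p = 0.148, 0.148 and 0.083) and passed it with adjusted p = 0.0197, 0.0344 and 0.0197 with an estimated correlation. In YYFF L8 vs L4, chromosome 16 (0.15) rose and chromosomes 15 (-0.08) and 17 (-0.12) fell, with adjusted p = 0.00158, 0.00283 and 0.00158 with an estimated correlation, and chromosome 12 rose (0.09, adjusted p = 0.0712 with an estimated correlation). Chromosome 10 (0.05) missed the threshold there with the preset correlation (adjusted p = 0.284) and passed with adjusted p = 0.0315 with an estimated correlation. In WT L4 vs L0 chromosome 15 rose (0.14, adjusted p = 0.00294 with an estimated correlation), and chromosome 12 fell (-0.17, adjusted p = 0.0573 with an estimated correlation). In WT L8 vs L0 chromosome 12 fell (-0.22, adjusted p = 0.0639 with an estimated correlation). Between the clones chromosome 12 was higher in YYFF at L8 (0.18, adjusted p = 0.0903 with an estimated correlation), and 0 of 20 chromosomes passed at L0 and at L4. The interaction passed for 0 of 20 chromosomes at L4 and at L8, so no chromosome-wide shift was shown to differ between the clones.

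**Figure D3:**
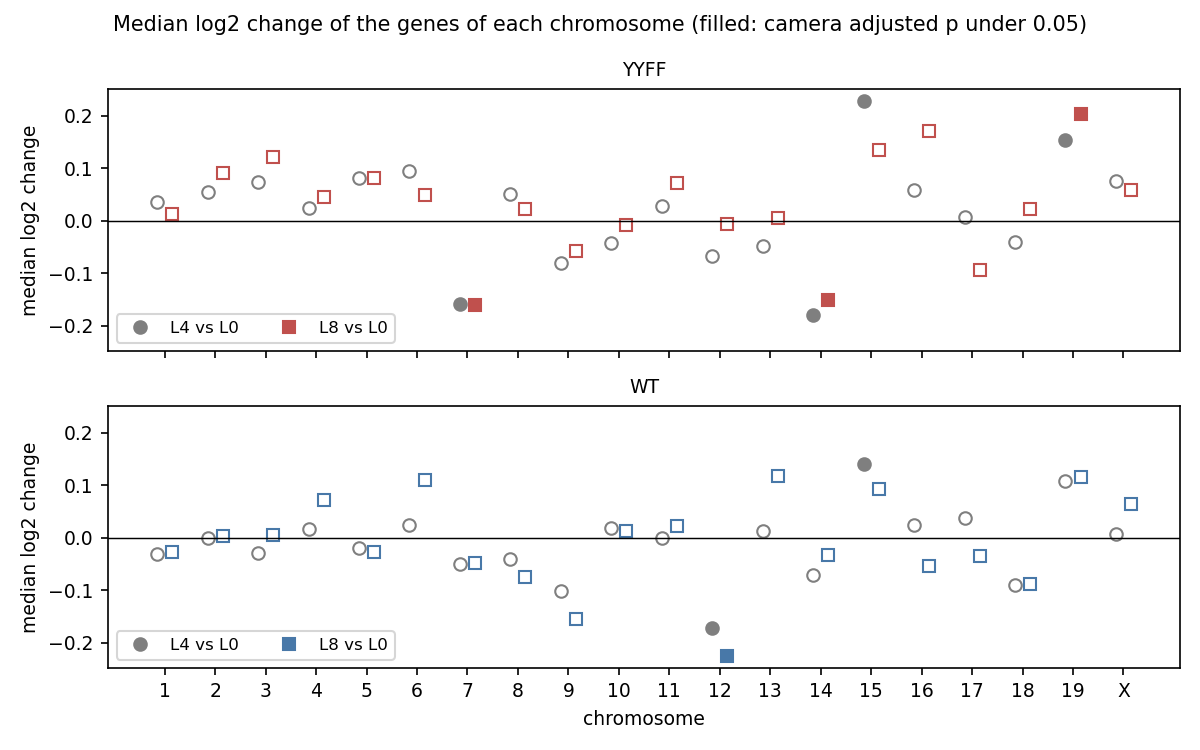
Median log2 change of the tested genes of each chromosome in L4 vs L0 (circles) and L8 vs L0 (squares), YYFF above and WT below, filled where the camera adjusted p with the preset correlation was under 0.05. All medians lie within -0.22 and 0.23.

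Within chromosome 19 the shift was uneven. In YYFF L4 vs L0 a stretch of 72 neighbouring tested genes from Ide to Neurl1a (GRCm38.p6 gene order) had a median log2 change of 0.67 with 71 genes above 0, and the following 35 genes, from Sh3pxd2a to Csf2ra, had a median of -0.39 with 28 below 0. The first 219 genes had a median of 0.09. In YYFF L8 vs L0 the same stretch and end had medians of 0.69 and -0.27, in YYFF L8 vs L4 of -0.02 and 0.02, and in WT L8 vs L0 of 0.15 and 0.06. The test behind this stretch, 8.96 against a highest value of 5.19 in 20 permutations of the gene order, was chosen after seeing the data and was run over 11 comparisons and 20 chromosomes. In WT L4 vs L0 the search split 5 chromosomes, 1, 2, 7, 9 and 10. It found 30 genes on chromosome 2, from Cbfa2t2 to Epb41l1, with a median of 0.56 and 29 above 0, and 22 genes on chromosome 10, from Ipmk to Pcbp3, with a median of 0.49. The search statistic was 6.81 on chromosome 2, but only 4.49 on chromosome 10 and 4.63 on chromosome 1. The highest permuted value was 4.45, so the splits of chromosomes 1 and 10 were marginal. On chromosome 9, 116 genes from Sc5d to Kif23 had a median of -0.26. On chromosome 7, 22 genes from Mrpl46 to Rccd1 had a median of 0.36 with 21 above 0, 65 genes from Myo7a to Mrpl17 had 0.28 and 48 genes from Apobr to Rgs10 had 0.30. In WT L8 vs L0 it found 60 genes on chromosome 13, from H2bc14 to Eci2, with a median of 0.50 and 53 above 0, a stretch that begins in a cluster of histone genes. Between the clones it split chromosomes 2, 7, 9, 13 and 19 at L4 and at L8, with chromosome 13 at L4 marginal (4.76 against 4.73). The search found no stretch in YYFF L8 vs L4 or between the clones at L0.

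**Figure D4:**
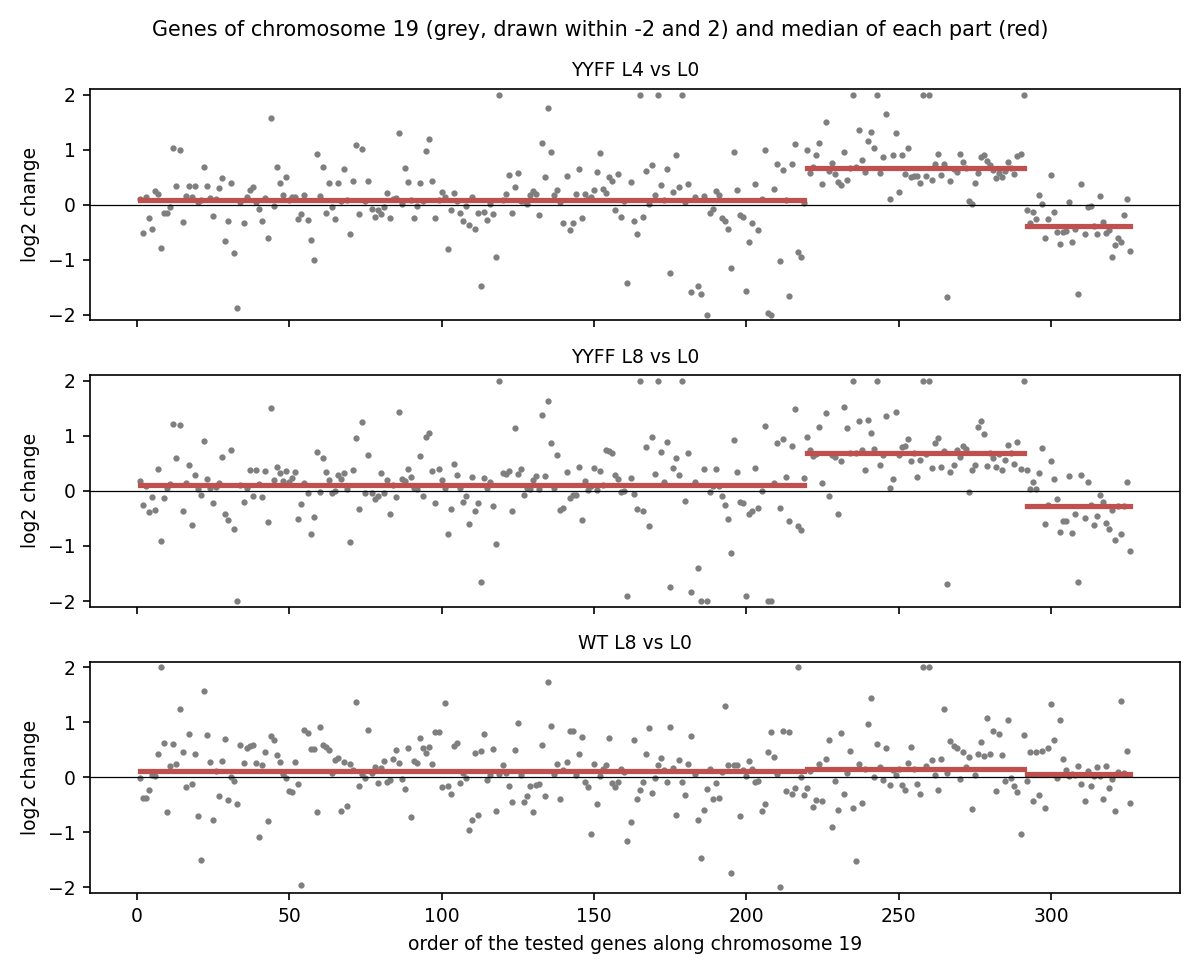
Log2 change of each tested gene of chromosome 19 in gene order (grey points, drawn within -2 and 2) in YYFF L4 vs L0, YYFF L8 vs L0 and WT L8 vs L0, with the median of each of 3 parts (red lines). The parts hold 219, 72 and 35 genes; the middle part has medians of 0.67, 0.69 and 0.15.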

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

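The tests on Y-linked genes, on the Xist probes, on blood cell markers, on gene families and on laminin passage, and the search for stretches of neighbouring genes, were chosen after the results were seen. Median scaling is a planned setting that was added to the tests of processing after the authors' values had been seen in them. In all, 14 tests of an explanation were run and 9 are given. A median of 0.705 over 2 blood cell markers was replaced by a count of markers, since the 2 genes go opposite ways and decide nothing. A median of 0.666 with 1 gene per name stem on chromosome 19 was replaced by a count of stems, since a stretch picked for its shift fixed it. The other 3 were left out after their results were seen, to keep each pattern to 3 explanations. For both X chromosomes being active in YYFF cells, which it argued against, the X-linked minus autosomal median at L0 was 0.0286. For a few strongly changed genes on chromosome 19, 98.6% of the stretch was above 0, which restates how the stretch was found and decides nothing. For processing as the source of the interferon change, the median in YYFF L4 vs L0 was -1.77 in the authors' values, which are also quantile-normalized, and -2.61 with median scaling, both against it.

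The genes and gene lists in this paragraph stand out because the effect of passage differed between YYFF and WT by the interaction test. It did for 2109 genes from L0 to L4 and for 2831 from L0 to L8. From L0 to L4 the difference in log2 change was 5.0 for Scara3, 4.53 for the creatine kinase Ckb, 4.49 for Plxna2 and 4.33 for Fez1. It was -6.91 for Ifi27l2a, -6.80 for Ptn, -6.09 for Rspo2 and -5.65 for Ogn. From L0 to L8 it was 4.56 for Scara3, 4.22 for Plxna2, 3.87 for Ramp2 and 3.84 for Fez1. It was -6.79 for Ogn, -5.34 for Cxcl12, -5.25 for Hs3st3a1 and -5.23 for Ppbp. Among gene lists from L0 to L4, the median difference was -1.68 for interferon response and 1.60 for cholesterol synthesis. It was -1.30 for chemokines and inflammatory genes (adjusted p = 0.0618 with an estimated correlation), -0.27 for matrix proteases (adjusted p = 0.0862 with an estimated correlation) and -0.52 for serum response and contractile genes (adjusted p = 0.0982 with an estimated correlation). For p53 targets it was -0.30 and for heat shock genes 0.44 (each adjusted p = 0.174 with an estimated correlation). From L0 to L8 it was -0.71 for p53 targets (adjusted p = 0.403 with an estimated correlation). Stretches of neighbouring genes were found by the search on the interaction differences, not by the interaction test. For whole chromosomes that test passed for 0 of 20 at L4 and at L8. Only stretches with a median beyond 0.3 are given, a limit set after they were seen. The median difference from L0 to L4 was 0.58 for Ide to Neurl1a and -0.40 for Sh3pxd2a to Csf2ra on chromosome 19. From L0 to L8 it was 0.62 for Marchf5 to Sh3pxd2a and -0.39 for Stn1 to Csf2ra on chromosome 19, and -0.75 for Zscan26 to H1f2 on chromosome 13. The chromosome 13 stretch ends at a histone gene, and gene families were not tested there. Its search statistic was 5.18, against a highest permuted value of 4.73.

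Xist was above background on every WT array and no YYFF array. A failed probe is argued against by the second Xist probe, since 2 of 2 probes were above background on every WT array and no YYFF array. A Y chromosome in the YYFF cells is argued against by Eif2s3y, Kdm5d and Zfy1, of which 0 of 3 were above background on any YYFF array. Uty, dim on all 12 arrays of both genotypes, was left out of that test once this was known. All cells are labelled female, so no array shows that these probes would detect the genes. Cells of male origin that had lost the Y chromosome are not excluded by this test. A single X chromosome in the YYFF clone may account for it: 5 of 7 genes known to escape X inactivation were tested, and their median difference in YYFF vs WT at L0 was -0.645, as low as in 7 of 10000 random lists. Of these, Pbdc1 (-0.51 ± 0.11), Eif2s3x (-0.79 ± 0.11) and Kdm6a (-0.64 ± 0.11) passed the test, while Ddx3x (adjusted p = 0.144) and Kdm5c (adjusted p = 0.525) did not, and no DNA measurement was analysed here.

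On chromosome 19, genes from Ide to Neurl1a were higher and genes after them lower in YYFF after laminin passage. Processing is argued against by the shift of the stretch above the first part of the chromosome in YYFF L4 vs L0, which was 0.473 in the authors' values and 0.571 with median scaling, against 0.581 here. Gene families are argued against, since its 72 genes have 67 different name stems. A change in copy number of the stretch stays open and was not decided: the lower of the medians of its brighter and dimmer genes was 0.67, but with a lower quartile of 0.528 in a stretch picked for its shift it could hardly have come out otherwise, and no DNA measurement was analysed here. The stretch had the highest search statistic, 8.96, over 11 comparisons and 20 chromosomes, though not the largest median.

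Interferon response genes fell and cholesterol synthesis genes rose in YYFF between L0 and L4 and in WT between L4 and L8. A labelling or array batch behind most of the change of all genes is argued against by the 8843 genes outside both lists. Over these genes the changes correlated with r of 0.165. A smaller shared shift is not excluded. For YYFF L4 vs L0 and WT L8 vs L0, simulated unchanged groups gave an r of at most 0.0449. Nor is a batch excluded that moved mainly the genes of both lists. Loss of blood cells is argued against by their markers: of 13 with a probe, 11 were above background on 0 of 12 arrays, among them the abundant transcripts Lyz2, Tyrobp, Laptm5 and Ptprc. The other 2 were Cd14 (1.71 ± 0.15 in YYFF L4 vs L0), above background on 12 arrays, and Coro1a (-0.30 ± 0.20), on 5. Passage on laminin cannot be told apart from time in culture, since 0 comparisons have cells kept as long without laminin.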

How the results depend on the processing

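The authors' values with all columns quantile-normalized and the mean-variance trend with a robust prior were chosen after the data were seen. Every named-gene result was past the threshold in the main fit. The largest changes were also picked for passing with any 1 array left out. The named-gene counts that follow were thus partly fixed by the choice of genes and do not describe genes in general. No named-gene result reversed: of 12428 values for 795 named-gene results, 11618 kept their direction and side of the threshold and 810 kept their direction but missed it. The majority of calls, which no test covers, turned in 8 cases: to 1129 higher and 1098 lower (YYFF L4 vs L0), 1344 and 1200 (YYFF L8 vs L0), 623 and 610 (WT L4 vs L0) and 965 and 985 (YYFF vs WT at L0) with the stricter filter, 1642 and 1696 (WT L8 vs L0) with the authors' values, 1207 and 1064 (YYFF vs WT at L4) with median scaling, and 485 and 443 without WT L4 replicate 1 and 429 and 422 without WT L4 replicate 2 (WT L4 vs L0). All 11 gene counts stayed within 1.5 times under no background correction, no filter, both forms of the authors' values, every probe and both replicate blocks. For results that moved, the cause was not tested, except that the compared arrays alone and arrays left out leave fewer residual degrees of freedom. With median scaling the counts were 1789 (YYFF L4 vs L0), 69 (YYFF L8 vs L4), 683 (WT L4 vs L0), 2068 (WT L8 vs L0), 865 (WT L8 vs L4), 1418 (YYFF vs WT at L0), and 1295 and 1753 (interaction at L4 and L8). YYFF L8 vs L4 gave 201 with the stricter filter, 71 with array weights, 259 with the trend and robust prior, and 0 by limma with the compared arrays alone (1082 at an unadjusted p under 0.05), where WT L4 vs L0 gave 490 and WT L8 vs L4 gave 890. The array weights were equal for the 2 arrays of each group, 0.549 in YYFF L8 and 1.36 in YYFF L4. They thus weighed whole groups and could not mark a single poor array. With an estimated correlation the shifted chromosomes were 6 (YYFF L8 vs L0), 1 (WT L4 vs L0), 0 (WT L8 vs L0) and 0 (YYFF vs WT at L8). The shifted lists were 4 (YYFF L4 vs L0), 4 (YYFF L8 vs L0), 0 (WT L4 vs L0), 2 (WT L8 vs L0), 1 (YYFF vs WT at L0) and 0 (YYFF vs WT at L8). With 1 array left out, and the lone array assumed to vary like the other groups, YYFF L8 vs L4 gave 35 (without YYFF L4 replicate 1) to 213 (without YYFF L8 replicate 2), and 45 without YYFF L4 replicate 2. WT L4 vs L0 gave 740 (without WT L0 replicate 1) to 928, with 843 without WT L0 replicate 2 and 851 without WT L4 replicate 2. WT L8 vs L4 gave 887 (without WT L8 replicate 2) to 1218, with 1023 without WT L8 replicate 1 and 1132 without WT L4 replicate 2. YYFF vs WT at L0 gave 1505 (without YYFF L0 replicate 1) to 1689, with 1526 without YYFF L0 replicate 2 and 1554 without WT L0 replicate 1. Shifted lists numbered 5 (without YYFF L4 replicate 2) to 11 in YYFF L4 vs L0, 3 to 9 (without WT L0 replicate 2) in WT L4 vs L0, 5 (without WT L0 replicate 1) to 8 in WT L8 vs L0, and 0 (without WT L8 replicate 1) to 4 in YYFF vs WT at L8. Deviations of arrays that share a replicate number correlated with r of 0.0248 to 0.354 by the titles (median 0.179, 13 of 15 pairs over 0.1), so that each correlated best with its own number, a hint from the data that the labels do not give. By the descriptions the r was -0.354 to 0.232 (5 of 15 over 0.1). The main model has no replicate block, since the labels tie no number to a shared batch and titles and descriptions differ. A replicate effect shared across groups stays possible, since all 15 correlations by the titles were above 0. The replicate block by the titles raised 11 of 11 gene counts and by the descriptions lowered 11 of 11. By the titles it ended the call of interferon response genes in YYFF vs WT at L8 (adjusted p = 0.0541) and of imprinted genes in WT L4 vs L0 (0.0588). A block for the bead chip was not run, since the sources used here name no chip. Signal over background limits the genes seen: 40.4% to 45.8% of probes were above it.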

Other observations

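Lists tied to adhesion and division did not pass the list test in YYFF L8 vs L0, where 36.4% of all genes tested changed. Of 12 integrin genes 2 rose and 4 fell (median -0.30, adjusted p = 0.291), with the collagen receptor subunit Itga11 at -3.46 ± 0.18, Itgb4 at -2.22 ± 0.21, Itgb7 at 3.32 ± 0.22 and Itga7 at 2.98 ± 0.16. In WT L8 vs L0 Itga11 rose by 3.79 ± 0.18 and Itgb4 by 1.08 ± 0.21. Of 15 focal adhesion genes 3 rose and 6 fell (7 adjusted over the list alone; median 0.02, mean -0.15, adjusted p = 0.452), with Fermt2 at -1.46 ± 0.12 and paxillin, Pxn, at 1.28 ± 0.22. Of 24 cytokinesis genes 6 rose (7 adjusted over the list alone) and 3 fell (median 0.25, adjusted p = 0.196), among them the nonmuscle myosins Myh9 (-0.78 ± 0.12) and Myh10 (-0.69 ± 0.15) and the midbody gene Cep55 (1.16 ± 0.25). Of 21 mitotic spindle and checkpoint genes 5 rose and 1 fell (3 and 1 adjusted over the list alone; median 0.27, adjusted p = 0.0706).

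Of 21 Hox genes, which mark position along the body, 6 rose and 3 fell (median 0.18, adjusted p = 0.291), with Hoxb4 at 1.98 ± 0.14, Hoxb7 at -1.80 ± 0.09 and Hoxd10 at -1.41 ± 0.12. Of 24 matrix proteases and inhibitors 4 rose (5 adjusted over the list alone) and 11 fell (median -0.17, adjusted p = 0.141), among them Adam19 (-4.41 ± 0.17) and Mmp23 (-3.13 ± 0.13). Of 32 DNA replication genes 5 rose and 1 fell (2 and 0 adjusted over the list alone; median 0.10, adjusted p = 0.21). The search also found stretches that were lower in YYFF than in WT at L8 on chromosome 7: 26 genes from Mrpl46 to Blm with a median of -0.81 and 53 genes from Sbk1 to Kat8 with a median of -0.80. In L8 vs L0 their medians were 0.22 and 0.14 in WT and -0.19 and -0.22 in YYFF. In WT L4 vs L0 they were 0.34 and 0.27, and at L0 YYFF vs WT gave -0.19 and -0.26. Changes of neighbouring genes correlated with r of 0.0558 to 0.113 in 10 of 11 comparisons, against at most 0.0302 in 100 permutations of the gene order. In YYFF L8 vs L4 the r was 0.0270, against a highest permuted value of 0.0266.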
